A study of Mus musculus with 40 samples.

How the data were processed

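The series holds 40 samples of mouse embryonic fibroblasts that lack GADD34, the product of Ppp1r15a. Cells were untreated or treated with thapsigargin at 1 uM for 0.5, 1, 2 or 4 h. Thapsigargin empties the calcium store of the endoplasmic reticulum (ER) and causes ER stress. Cells were opened with digitonin, which releases the cytosol, and the rest was extracted with dodecyl maltoside, which gives the ER fraction. Ribosome footprints (after a digest with micrococcal nuclease) and mRNA (after removal of ribosomal RNA) were sequenced from each fraction, per the labels' protocols. Each of the 20 combinations of assay, fraction and time has 2 samples, numbered 1 and 2. The labels do not say whether these came from separate cultures, so the p-values measure only the spread between these samples. No wild-type sample is among them, so no comparison below is of genotypes.

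The authors deposited 1 table of 22417 mouse RefSeq genes with 1 column of RPKM values per sample. The submitters' processing notes name Bowtie without a version and the build hg19, which is a human build, although the genes in the table are mouse genes. No coordinates are given here for that reason. The 4 header lines give assay, replicate, fraction and time and no unit. The unit was read from the values: for all 13206 genes listed in 2 or more libraries, the values were whole numbers times 1 factor per library, divided by a length, within 2e-05 plus a 1e-09 share of the number itself. The whole numbers were taken as read counts, which the authors did not deposit. Column 16 of the table, ER footprints at 0.5 h, replicate 2, is empty, so 39 libraries were used. A further column without a header marks 8434 genes TRUE and 13983 FALSE. It is written here as the mark of the deposited table. Among the gene lists described below, 39 of 40 matrix and secreted genes, 35 of 36 receptors and 25 of 27 ER chaperones are TRUE. Of 35 abundant cytosolic proteins, 82 ribosomal proteins and 47 histones 0 are.

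The table holds no zeros. A gene without a value in a library is left blank, and blanks were read as not measured. Footprint libraries and mRNA replicate 1 libraries list a gene from 4 recovered reads on, and mRNA replicate 2 libraries from 1. The deposited RPKM values also carry a weight per fraction and time. In mRNA replicate 2 the ER weight was 46.0% in untreated cells and 33.9%, 39.0%, 43.0% and 48.0% at 0.5, 1, 2 and 4 h, with the remainder to 100% in the cytosol. This weight was inferred from the values and is not described in the labels. It moves a log2 change in mRNA replicate 2 by -0.44, -0.24, -0.10 and 0.06 in the ER at the 4 times and by 0.29, 0.18, 0.08 and -0.05 in the cytosol, with replicate 1 within 0.01 of these. In footprints replicate 1 it moves one by -0.51, -0.29, -0.21 and -0.02 in the ER and by 0.33, 0.21, 0.16 and 0.02 in the cytosol. In footprints replicate 2 at 1, 2 and 4 h the moves are -0.29, -0.09 and 0.03 in the ER and 0.20, 0.07 and -0.03 in the cytosol. The planned design took each library to be scaled to its own total, and the fit without the weight is given as an alternative. That fit divides every library, footprints included, by the weights of mRNA replicate 2. Where the footprint weights differ from these, the difference stays in the values.

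Recovered reads per library ran from 56857 to 9604852 in ER footprints (median 140366) and from 122242 to 5388188 in cytosol footprints (median 476440). They ran from 1502 to 162032 in ER mRNA and from 48215 to 315658 in cytosol mRNA. In mRNA libraries the 10 largest genes held 35.2% to 79.2% of the RPKM, led by the loci LOC101056226, LOC101055971 and C330021F23Rik. In footprint libraries they held 8.5% to 17.9%. Spearman correlations across genes between the 2 libraries of a group were 0.88 to 0.92 in footprints and 0.64 to 0.74 in mRNA. Genes are not independent replicates. For 34 genes the values equal those of another gene of the table, so their reads cannot be told apart.

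Each comparison was fitted with limma (version 3.58.1 in R 4.3.3, trend on, robust off) on log2(RPKM + 1), for genes with a mean of at least 1 RPKM over the libraries of the fit. Blanks count as 0 in that mean only. A gene was tested in a contrast where every library of the groups compared listed it. Adjusted p-values are Benjamini-Hochberg, 2-sided, with a threshold of 0.05. The 5 times of 1 assay and 1 fraction shared a fit. Translational efficiency, the ratio of footprints to mRNA, was tested as an interaction over both assays of 1 fraction. The ER-to-cytosol ratio in untreated cells, and its change with thapsigargin (the shift), were tested over both fractions of 1 assay. Changes include the shift of the median gene, which is given with each comparison. RPKM values are scaled to the reads of their library, with the weight per fraction on top. A rise or fall is thus relative to the other genes and not a change in absolute amount. Total translation and total mRNA of the cells cannot be read from these values.

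Before the data were examined, 27 gene lists were fixed; 719 of their 732 genes are in the table, and none of the 13 genes of the mitochondrial genome is. Lists with at least 4 measured members were tested with camera (limma) with a preset correlation of 0.01, and again with an estimated one, with Benjamini-Hochberg adjustment over all lists and contrasts of 1 family (mRNA over time, footprints over time, translational efficiency, fractions). Over all comparisons 580 list tests were made. The named genes follow a rule fixed at the same time. It takes Ppp1r15a, Ppp1r15b and a panel of 18 stress, matrix and reference genes. It adds the 6 largest rises and 6 largest falls past the threshold whose replicates separate and whose level is at least the median, without predicted genes. It also adds up to 4 members per list, which are at most 2 up and 2 down, or the 2 with the highest level where none passes. Genes named outside it are said to be so.

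Same-numbered libraries were checked for pairing by the correlation of the difference between replicates across groups. It was over 0.1 for every pair of groups in ER mRNA (0.35 to 0.70) and cytosol mRNA (0.61 to 0.74). The same held in ER footprints (0.18 to 0.38) and the mRNA of both fractions (0.35 to 0.74). In these fits same-numbered libraries share a difference, called pairing here, and the fit with a replicate block is given where it changes a call. Whether they share a culture or a way of library making is not in the labels. The mRNA replicates differ in listing minimum. In untreated mRNA replicate 1 listed 39 histones in the ER and 37 in the cytosol, and replicate 2 listed 4 and 3. In the mRNA fits without a block this difference is part of the spread. In cytosol footprints (-0.19 to 0.63) and in the remaining fits the correlation was not over 0.1 for every pair of groups.

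Alternatives were median centring, no filter on low values, pseudocounts of 0.1 and 5, a replicate block (in the fits over 2 assays or 2 fractions also 1 per time) and leaving out each library. Added after the data were seen were blanks read as 0, a mean of at least 50 RPKM with blanks read as 0, removal of 2 libraries in doubt (cytosol footprints 0.5 h replicate 2 and ER mRNA 0.5 h replicate 2), limma voom on the recovered reads with median-ratio size factors, removal of the weight per fraction, and a block with centring or per assay. A gene that fell below the listing minimum in a shallow library is not tested, which favours genes that rose, so counts at a mean of at least 50 RPKM stand beside the footprint counts.

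The fits were tested on simulated negative binomial reads with the libraries' own depths and mean shares and a spread taken from their replicates. Changed genes were drawn only from genes whose expected reads lay far above the listing minimum in every library compared. The recovery below is that of well-covered genes, and tested genes of lower coverage may be recovered less often. At 4 h the ER footprint fit recovered 76% of 100 genes changed 4-fold and 9% of 100 changed 2-fold, and called 12 of 2278 unchanged genes. The cytosol footprint fit recovered 34% and 5%, with 3 of 3864 unchanged genes called beside 33 and 5 true calls. The shift of footprints recovered 24.2% and 1%, and the ER-to-cytosol ratio of footprints 55% and 6%. ER translational efficiency recovered 16.3% and 0%. Both mRNA time fits, the mRNA ratio and shift between fractions, and cytosol translational efficiency recovered 0% at either size. The simulated libraries were drawn independently and fitted without a block, so the pairing of same-numbered libraries was not simulated. Recovery and false calls of the fits with a replicate block are therefore not known. Recovery of reads and permutation tests used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.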

Results

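Ribosome footprints and mRNA were measured in mouse embryonic fibroblasts that lack GADD34, a protein that directs the removal of phosphate from the initiation factor eIF2alpha. Each assay was run on an ER and a cytosol fraction of untreated cells and of cells after 0.5, 1, 2 and 4 h of thapsigargin, an inhibitor of the calcium pump of the endoplasmic reticulum. This gave 20 groups with 2 libraries each. The library of ER footprints at 0.5 h, replicate 2, has no values, so that group has 1 library and 39 libraries remain.

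Recovered reads in ER footprints of replicate 1 were 9604852 in untreated cells and 140366, 217963, 66151 and 56857 at 0.5, 1, 2 and 4 h. In replicate 2 they were 396445 in untreated cells and 102268, 292071 and 125523 at 1, 2 and 4 h. Cytosol footprints of replicate 1 had 272300, 1590371, 1114566, 337388 and 122242 reads in the same order of times, and those of replicate 2 had 5388188, 234731, 686549, 351393 and 601488. ER mRNA had 162032, 106331, 144142, 115260 and 151391 reads in replicate 1 and 64804, 1502, 84290, 64498 and 31675 in replicate 2. Cytosol mRNA had 258536, 231625, 279250, 295515 and 315658 reads in replicate 1 and 48215, 163215, 110738, 208406 and 174070 in replicate 2.

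Ppp1r15a (NM_008654), the gene of GADD34, was listed in 2 of 39 libraries. ER footprints of untreated cells, replicate 2, gave 2.89 RPKM from 5 reads. The library labelled cytosol footprints 0.5 h, replicate 2, gave 19.26 RPKM from 14 reads. The labels do not say which part of the gene was deleted, so these reads do not check the genotype. Its paralog Ppp1r15b was listed in 32 of 39 libraries, with a median of 8.98 RPKM and a range of 0.43 to 17.31.

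The first comparison asks which genes gained or lost footprints in the ER fraction during ER stress. Footprints of Ddit3, Atf4, Gadd45b and Gadd45g rose and those of most matrix and secreted proteins fell. Atf3 and Dnajb9 were not listed in every library of the groups compared, so the fit could not test them. Ddit3 (NM_007837), the cell death factor CHOP, went from 8.14 ± 4.43 RPKM (SD, n = 2) to 373 ± 41.8 RPKM (n = 2) at 4 h, a log2 change of 5.44 (SE 0.43, limma adjusted p = 3.7e-06). Atf4, the main transcription factor of the integrated stress response, went from 71.4 ± 28.2 to 1600 ± 698 RPKM, a log2 change of 4.45 (adjusted p = 6.7e-05). Col1a1, a chain of type I collagen, went from 4270 ± 1310 to 755 ± 288 RPKM, a log2 change of -2.52 (adjusted p = 0.00096). At 0.5 h, where the only library (n = 1) takes its spread from the other groups, Ddit3 had a log2 change of 3.55 (adjusted p = 0.032), and 0 genes passed there without either untreated library. Atf4 passed the test from 1 h on (4.06, adjusted p = 0.00046).

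At 4 h the 6 largest rises under the naming rule were Hist1h1a at 5.76, Gadd45b at 5.69, Gadd45g at 5.48, Ddit3, Hist4h4 at 5.16 and Hist3h2a at 4.98. Gadd45b and Gadd45g encode stress sensors, and the others apart from Ddit3 encode histones. Hist1h1a went from 177 ± 6.47 to 10600 ± 6290 RPKM, and Gadd45b from 48.8 ± 1.27 to 2640 ± 883 RPKM. Of 45 measured replication-dependent histones, whose mRNAs end without a poly(A) tail, 44 rose, 0 fell and 1 did neither (median log2 change 3.13, set adjusted p = 1.2e-23, 44 up adjusted over the list alone). Of 14 immediate early genes 13 rose and 1 did not pass (median 2.71, set adjusted p = 2.7e-08, 13 up adjusted over the list alone), with Klf10 at 4.71. Of 10 mRNAs described as translated through upstream open reading frames when eIF2alpha is phosphorylated, 6 rose and 4 did not pass (median 2.16, set adjusted p = 0.0031, 6 up adjusted over the list alone), among them Atf5 at 4.49. Of 8 NF-kB and cytokine genes 4 rose and 4 did not pass, with the same 4-up count adjusted over the list alone. They include the inhibitor Nfkbia at 4.55 and the chemokine Ccl7 at 4.97, or 2.54 without untreated replicate 1 (median 2.09, set adjusted p = 0.041, adjusted p = 0.54 with an estimated correlation). Their median was 0.84 without untreated replicate 1 and 1.35 without thapsigargin replicate 2, and neither set test then passed 0.05 before adjustment.

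The 6 largest falls were the lipoprotein receptor Lrp1 at -3.08, Col2a1 at -3.06, Col6a3 at -2.92, the integrin Itgb1 at -2.87, fibronectin Fn1 at -2.79 and Col3a1 at -2.77. Of 36 matrix and secreted proteins 31 fell, 0 rose and 5 did neither (median -1.77, set adjusted p = 5.2e-24, 32 down adjusted over the list alone), with 19 and 20 down without untreated replicates 1 and 2. Of 25 receptors and transporters 12 fell and 13 did not pass (median -1.12, set adjusted p = 8.8e-11, 13 down adjusted over the list alone). Fibroblast markers had 4 of 8 down and 4 not past the test (median -0.86, set adjusted p = 0.0013, 4 down adjusted over the list alone; median -0.47 without thapsigargin replicate 1). Of 4 measured mRNAs described as cleaved by IRE1 3 fell, with Pdgfrb at -2.25 and Col6a1 at -2.23 (median -1.93, set adjusted p = 0.0058, 3 down adjusted over the list alone). Without thapsigargin replicate 1, 10 of these mRNAs were measured, with 1 up, 3 down and a median of -0.15, and without untreated replicate 2 2 fell.

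ER chaperones divided. Hspa5, the ER chaperone BiP, rose from 924 ± 217 to 2000 ± 120 RPKM (log2 change 1.13, adjusted p = 0.034, but 0.092 with median centring), a call that was lost when any 1 of the 4 libraries was left out. The protein disulfide isomerases P4hb and Txndc5 fell, at -2.07 and -2.15, although the list is one of proteins made in ER stress. Of 20 chaperones 1 rose, 5 fell and 14 did neither, with the same counts adjusted over the list alone (median -0.96, set adjusted p = 4.3e-06), and 3 and 2 fell without untreated replicates 1 and 2. Hsp90b1 had -0.99 (adjusted p = 0.065, but 0.021 with the replicate block and 0.028 with median centring), Xbp1 1.01 (0.08, but 0.037 with the block) and Sdf2l1 1.06 (0.088, but 0.031 with the block). Manf was at -0.51 and did not pass. The translocation and transport list had 1 up, 6 down and 19 neither of 26, and 10 down adjusted over the list alone, with Ssr1 at -2.23 and Sec61b up at 1.54 (median -0.85, set adjusted p = 2.4e-05, adjusted p = 0.077 with an estimated correlation; median centring gave Sec61b an adjusted p of 0.054). Its median was -0.53 without thapsigargin replicate 2, and its falls were 1 and 3 without thapsigargin replicates 1 and 2 and 2 without untreated replicate 2. ER-associated degradation had 1 of 11 up, Herpud1 at 1.55, and 10 not past the test, with 1 up adjusted over the list alone (median -0.38, set adjusted p = 0.28). This median was -0.71 and 0.36 without untreated replicates 1 and 2 and 0.47 without thapsigargin replicate 2. Herpud1 did not pass without untreated replicate 1 or thapsigargin replicate 2, and neither did Sec61b, which was also lost without thapsigargin replicate 1.

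Targets of ATF4 and CHOP had 10 of 26 up and 16 not past the test, with 10 up adjusted over the list alone (median 0.56, set adjusted p = 0.23). Chac1, which degrades glutathione, rose by 3.67 and Trib3 by 1.65, while Asns was at -0.64 and did not pass. Of 19 tRNA synthetases 5 rose and 14 did not pass, with 4 up adjusted over the list alone, among them Sars at 1.45 and Yars at 1.42 (median 0.34, set adjusted p = 0.93). Trib3, Sars and Yars did not pass without either untreated library. Of 34 translation factors 3 rose, 5 fell and 26 did neither, with the same counts adjusted over the list alone (median -0.01, or -0.04 to 0.08 without 1 library, set adjusted p = 0.14). The helicase Eif4a2 was up at 3.86, and the elongation factor Eef1b2 and the poly(A) binding protein Pabpc1 were down at -2.36 and -1.81. The falls of this list were 3 and 1 without untreated replicates 1 and 2 and 1 and 3 without thapsigargin replicates 1 and 2.

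Ribosomal proteins had 5 up, 5 down and 69 neither of 79, and 2 up adjusted over the list alone (median -0.11, set adjusted p = 0.0058, adjusted p = 0.08 with an estimated correlation). Abundant cytosolic proteins had 1 up, 4 down and 30 neither of 35, and 2 down adjusted over the list alone (median -0.16, set adjusted p = 0.0058, adjusted p = 0.28 with an estimated correlation). Without untreated replicates 1 and 2 and thapsigargin replicates 1 and 2, ribosomal proteins had 3, 1, 3 and 1 up and 0, 0, 0 and 2 down, cytosolic proteins had 1, 2, 1 and 2 down, and the cell cycle list had 0, 0, 1 and 0 up. The median of ribosomal proteins was -0.03 without untreated replicate 2, and that of cytosolic proteins 0.09 and -0.02 without replicate 1 of untreated and thapsigargin cells. The remaining measured lists did not pass as sets. The cell cycle list had 2 of 23 up, Mcm3 at 1.43 and Tk1 at 1.30 (adjusted p = 0.032, but 0.081 with median centring), and 0 adjusted over the list alone (median 0.27, set adjusted p = 0.61), with medians of 0.50 and 0.00 without untreated replicates 1 and 2 and of 0.07 without thapsigargin replicate 1. NRF2 targets had 1 of 10 up, Hmox1 at 2.05 (median 0.28, set adjusted p = 0.67), and sterol synthesis 1 of 10, Lss at 2.34 (median 0.32, set adjusted p = 0.85), with 1 up adjusted over the list alone in each. The p53 list had 4 of 9 up, with Cdkn1a at 1.80, and 1 down, Ccnd1 at -1.47 (median 0.14, set adjusted p = 0.82, the same counts adjusted over the list alone). Heat shock genes had 2 of 11 up and 1 down, the mitochondrial chaperone Hspd1 at -1.60 (median 0.13, set adjusted p = 0.67, the same counts adjusted over the list alone). The 2 that rose, Hspa1a at 2.09 and Hspa1b at 1.94, are near-identical copies, so their split is uncertain. The respiratory chain had 1 of 35 down, Atp5b at -1.22, and 0 adjusted over the list alone (median -0.04, set adjusted p = 0.082). The calls of Tk1, Hspd1 and Atp5b were lost when any 1 of the 4 libraries was left out, and that of Mcm3 without either untreated library or thapsigargin replicate 2. Of 2 measured muscle and neural markers neither Tubb3 at 0.87 nor Nes at -0.73 passed. Macrophage, epithelial and endothelial markers had no testable member here, and the genes of the mitochondrial genome are not in the table. The cell cycle, NRF2, sterol and heat shock lists had a positive median and a set test pointing down, because the median gene stood at 0.44. Translation factors, respiratory chain and ER-associated degradation had a negative median and a positive mean, with the test pointing down.

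Over all genes limma called 7 up and 4 down of 4893 at 0.5 h, 236 up and 240 down of 3633 at 1 h, 368 up and 185 down of 3252 at 2 h and 695 up and 214 down of 3162 at 4 h. Those at 0.5 h, named after their values were seen where outside the rule, include Ddit3, Gadd45b, Gadd45g, Hist1h2bb, Hist1h2bf, Hist1h2bp and Hist3h2a up, and Col5a1, Hspg2 and Pabpc1 down. Hist1h2bp and Hist3h2a are not in the histone list. The median gene stood at -0.19, -0.03, 0.19 and 0.44, and median centring gave 17 up and 4 down, 289 up and 186 down, 353 up and 243 down, and 521 up and 293 down. Without the weight per fraction there were 24 up and 2 down at 0.5 h and 345 up and 151 down at 1 h. The replicate block gave 63 up and 133 down at 0.5 h and 401 up and 467 down at 1 h. Among 1353 genes of at least 50 RPKM with blanks read as 0 the counts were 9 up and 3 down, 103 up and 59 down, 130 up and 63 down, and 158 up and 89 down. Over all genes with blanks read as 0 the balance turned to falls, with 20 up and 420 down at 0.5 h, 88 up and 551 down at 1 h, 139 up and 565 down at 2 h and 189 up and 645 down at 4 h. Both untreated ER libraries held more reads than any ER footprint library after thapsigargin. A low gene that is blank in a shallow library can therefore appear to fall in that fit through depth alone. The 11 calls at 0.5 h fell to 0 without either untreated library. The total at 1 h was 124 and 165 without untreated replicates 1 and 2, and 267 and 148 without thapsigargin replicates 1 and 2. At 2 h it was 145 and 136 without the untreated libraries and 310 without thapsigargin replicate 1, and at 4 h 489 and 529 without the untreated libraries.

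**Figure D1:**
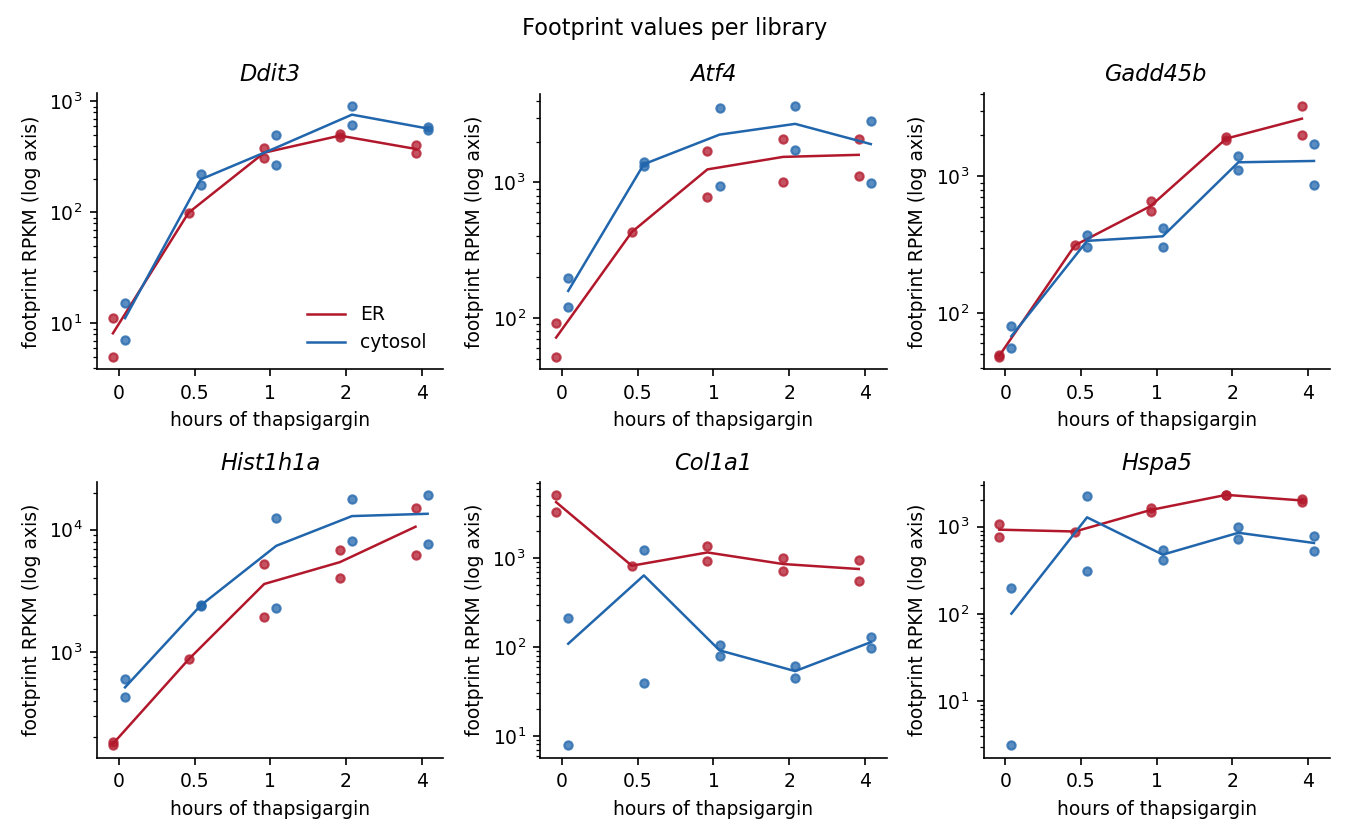
Footprint RPKM on a log axis against hours of thapsigargin for 6 genes, with 1 point per library, lines through group means, ER in red and cytosol in blue. Ddit3 in the ER went from 8.14 to 373 RPKM and Col1a1 from 4270 to 755 RPKM between untreated cells and 4 h.

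The second comparison asks the same of the cytosol fraction. Ddit3, Gadd45b and most replication-dependent histones rose here as well, and Fasn, Kif5b and Trim28 were among the genes that fell. Ddit3 went from 11.2 ± 5.73 (SD, n = 2) to 571 ± 30.4 RPKM (n = 2) at 4 h, a log2 change of 5.64 (SE 0.49, limma adjusted p = 0.0019). Fasn, the fatty acid synthase, went from 61.7 ± 29.9 to 4.27 ± 0.0641 RPKM, a log2 change of -3.48 (adjusted p = 0.013). After Ddit3 the largest rises were Hist1h2ae at 5.40, Hist4h4 at 5.35, Hist3h2a at 5.33, Hist1h2ab at 5.31 and Hist1h2bm at 4.87. The split of reads between near-identical core histone copies is uncertain here as well. After Fasn the largest falls were the kinesin Kif5b at -3.16, the actin regulator Twf1 at -3.09, the chromatin proteins Smarcc1 at -2.97 and Trim28 at -2.95, and Strap at -2.87. Hist3h2a and these 6 falls, Fasn included, did not pass without untreated replicate 2 or thapsigargin replicate 2.

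Of 45 histones 35 rose and 10 did not pass (median 3.37, set adjusted p = 2.1e-33, 45 up adjusted over the list alone). Of 17 immediate early genes 7 rose and 10 did not pass (median 1.70, set adjusted p = 1.6e-08, 12 up adjusted over the list alone), with Gadd45b at 4.17 and Klf10 at 3.81. Upstream reading frame mRNAs had 5 of 11 up and 6 not past the test, and 5 up and 1 down adjusted over the list alone, with Atf5 at 3.65 and Atf4 at 3.44 (median 1.93, set adjusted p = 0.00019, adjusted p = 0.061 with an estimated correlation). The cell cycle list had 3 of 29 down, with the kinesin Kif11 at -2.42 and the topoisomerase Top2a at -2.16, and 26 not past the test (median -0.66, set adjusted p = 0.0027, 6 down adjusted over the list alone). Abundant cytosolic proteins had 6 of 35 down, with the chaperonin subunit Tcp1 at -2.80 and Tuba1a at -2.19, and 12 down adjusted over the list alone (median -0.83, set adjusted p = 2.4e-06, adjusted p = 0.056 with an estimated correlation). Translation factors had Eif4a2 up at 2.93 and Eif2s3x, a subunit of eIF2, down at -2.41, and 33 of 35 not past the test, also adjusted over the list alone (median -0.64, set adjusted p = 0.034, adjusted p = 0.21 with an estimated correlation). Ribosomal proteins had 1 of 82 down, Rpl5 at -1.60, and 0 adjusted over the list alone (median -0.55, set adjusted p = 0.034, adjusted p = 0.68 with an estimated correlation). Without thapsigargin replicates 1 and 2 and untreated replicate 2, histones had 18, 8 and 5 up, upstream reading frame mRNAs 3, 1 and 1, immediate early genes 3 each, and cytosolic and cell cycle genes 0 down each. The cell cycle list also had 0 down without untreated replicate 1. Without untreated replicate 2 ribosomal proteins had a median of -0.31 and translation factors one of -0.43, and neither set test passed 0.05 before adjustment without that library or without thapsigargin replicate 1. Translation factors had a median of -0.42 without thapsigargin replicate 2.

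Lists of ER-bound proteins moved up, and untreated replicate 2 held far fewer of their footprints than untreated replicate 1. It gave 3.1 RPKM for Hspa5 against 198, 7.83 for Col1a1 against 210, and 3.51 for Fn1 against 138. ER chaperones had 1 of 19 up, Hspa13 at 2.66, and 5 up adjusted over the list alone (median 2.30, set adjusted p = 3.7e-06, adjusted p = 0.3 with an estimated correlation; median 0.89 without untreated replicate 2). Matrix and secreted proteins had 2 of 34 up, Ctgf at 3.80 and Timp1 at 3.18, and 1 up adjusted over the list alone (median 1.54, set adjusted p = 3.7e-05, adjusted p = 0.5 with an estimated correlation; median -0.23 and limma camera p = 0.3 without untreated replicate 2). Receptors had 0 of 20 past the test, also adjusted over the list alone (median 1.73, set adjusted p = 0.0002, adjusted p = 0.42 with an estimated correlation; median 0.73 and limma camera p = 0.11 without untreated replicate 2). ER-associated degradation had 1 of 9 up, Faf2 at 2.72, and 4 up adjusted over the list alone (median 1.81, set adjusted p = 0.0058, adjusted p = 0.35 with an estimated correlation). Translocation and transport had 5 up and 1 down of 33, and 8 up and 1 down adjusted over the list alone, with Ssr4 at 3.42, Kdelr2 at 3.22 and Sec24d at -1.93 (median 0.82, set adjusted p = 0.034, adjusted p = 0.44 with an estimated correlation). Without untreated replicate 1, 12 chaperones, 12 matrix genes, 6 receptors, 5 degradation genes and 11 translocation genes were up. Medians were then 3.65, 3.12 and 2.73 in chaperones, matrix genes and receptors and 1.49 in translocation genes. Without untreated replicate 2 or either thapsigargin replicate, 0 matrix, 0 degradation and 0 translocation genes were up. Hspa13 stood at 1.53 and Ctgf at 2.00 without untreated replicate 2. Without untreated replicate 2 the median was 0.12 in translocation genes, whose set test then did not pass 0.05 before adjustment, and 0.64 in degradation genes, and without thapsigargin replicate 1 it was 0.31 in translocation genes and 0.81 in receptors. NF-kB and cytokine genes had Csf1 up at 4.34, 1 of 6, and 2 up adjusted over the list alone (median 3.05, set adjusted p = 0.0035, adjusted p = 0.29 with an estimated correlation; median 1.75 without thapsigargin replicate 2). Xbp1, a transcription factor of the ER stress response, rose by 3.15 (adjusted p = 0.0092), a call that was lost without untreated replicate 2 or thapsigargin replicate 1. Hspa13, Faf2 and Csf1 did not pass without untreated replicate 2 or either thapsigargin replicate. Hspa5 had 4.49 (adjusted p = 0.089), Hsp90b1 3.11 (0.15), Manf 3.20 (0.055, but 0.031 with median centring) and Herpud1 2.47 (0.061, but 0.04 with centring), and none of these passed.

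Targets of ATF4 and CHOP had 4 of 25 up, with the amino acid carrier subunit Slc3a2 at 4.17 (2.65 without untreated replicate 2), and 4 up adjusted over the list alone (median 0.29, set adjusted p = 0.1). Of 3 measured IRE1 substrates 1 rose, Pmp22 at 3.80, and 2 adjusted over the list alone, too few for a set test. NRF2 targets had Hmox1 up at 2.04 and Txnrd1 down at -1.75 (adjusted p = 0.037, but 0.058 with median centring) of 11, and 1 up and 4 down adjusted over the list alone (median -0.52, set adjusted p = 0.3). Heat shock genes had 2 of 14 down, Hspd1 at -2.23 and Dnaja1 at -2.11, and 3 adjusted over the list alone (median -0.35, set adjusted p = 0.13). The p53 list had 1 of 9 down, Ccnd1 at -2.17, also adjusted over the list alone (median 0.00, mean -0.28, set adjusted p = 0.82). The respiratory chain had 1 of 44 down, Atp5f1 at -1.97, and 0 adjusted over the list alone (median -0.33, set adjusted p = 0.64). With 0 past the test, also adjusted over the list alone, were 20 tRNA synthetases (median -0.22, set adjusted p = 0.32), 9 sterol synthesis genes (median 0.25, set adjusted p = 0.38) and 5 fibroblast markers (median 0.78, set adjusted p = 0.68). The fibroblast median was 2.61 and -0.63 without untreated replicates 1 and 2 and 0.31 and 1.47 without thapsigargin replicates 1 and 2. Slc3a2, Pmp22, Hmox1, Txnrd1, Hspd1, Dnaja1, Ccnd1 and Atp5f1 did not pass without untreated replicate 2 or thapsigargin replicate 2. Of epithelial markers only Krt19 was measured, at -0.40, and it did not pass.

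Over all genes limma called 141 up and 2 down of 5369 at 0.5 h, 73 up and 2 down of 6225 at 1 h, 294 up and 308 down of 4971 at 2 h and 199 up and 163 down of 4602 at 4 h. The falls at 0.5 h were Cpsf2 and Nek6, and those at 1 h were Cpsf2 and Klhl9, all named after their values were seen. The median gene stood at -0.03, -0.15, -0.14 and -0.12. Among 1831 genes of at least 50 RPKM with blanks read as 0 the counts were 141 up and 0 down, 113 up and 4 down, 195 up and 75 down, and 161 up and 116 down. Over all genes with blanks read as 0 they were 87 up and 1 down, 71 up and 1 down, 163 up and 55 down, and 169 up and 59 down. The voom fit gave 521 up and 181 down, 414 up and 57 down, 542 up and 173 down, and 637 up and 288 down. At 0.5 h the total was 474 without untreated replicate 1 and 0 without untreated replicate 2 or either thapsigargin replicate. At 1 h it was 420 without untreated replicate 1, 0 without untreated replicate 2 or thapsigargin replicate 2, and 48 without the library labelled cytosol footprints 0.5 h, replicate 2. At 2 h it was 5 and 32 without thapsigargin replicates 1 and 2 and 49 without untreated replicate 2. At 4 h it was 64 and 20 without thapsigargin replicates 1 and 2, and 14 without untreated replicate 2.

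**Figure D2:**
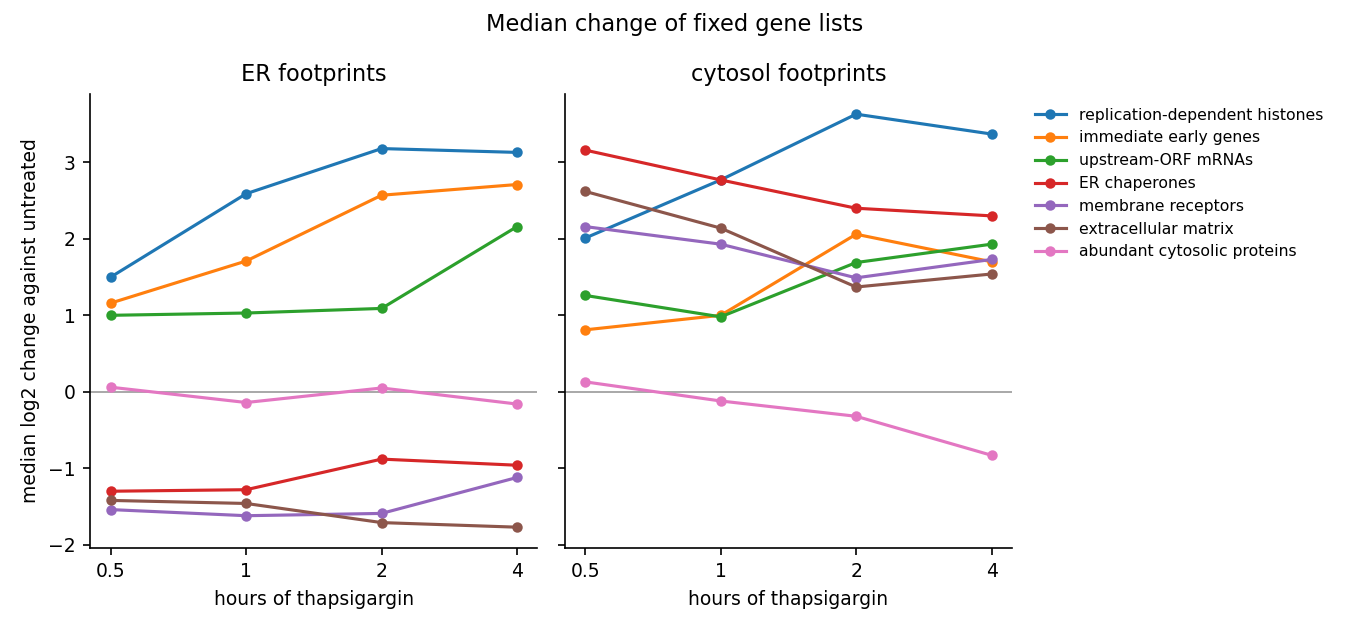
Median log2 change of footprints against untreated cells (vertical axis) at each time of thapsigargin for 7 fixed gene lists, with the ER fraction on the left and the cytosol on the right. At 4 h matrix and secreted proteins stood at -1.77 in the ER, while histones stood at 3.13 in the ER and 3.37 in the cytosol.

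The third comparison asks which footprints were in the ER fraction in untreated cells. Genes of secreted, membrane and ER proteins were far higher in the ER, and Cks2, Psma5 and Rps27a were among the genes higher in the cytosol. Col1a1 had 4270 ± 1310 RPKM in the ER (SD, n = 2) and 109 ± 143 RPKM in the cytosol (n = 2), a log2 ratio of 6.60 (SE 1.30, limma adjusted p = 0.0043). The next largest were Col1a2 at 6.21, the growth factor binding protein Igfbp2 at 6.12, Col2a1 at 5.64, thrombospondin Thbs1 at 5.63 and P4hb at 5.58. Hspa5 stood at 5.00 (adjusted p = 0.012) and Hsp90b1 at 5.11 (0.0052). These sizes rest on cytosol replicate 2, which gave 3.1 RPKM for Hspa5 and 7.83 for Col1a1 against 198 and 210 in replicate 1. Without it Hspa5 stood at 2.20 (adjusted p = 0.11), Hsp90b1 at 2.71 (0.05, not past the test), Col1a1 at 4.31 (0.062), P4hb at 3.32 (0.074) and Col2a1 at 5.03 (0.051), while Col1a2 at 3.98 (0.032), Igfbp2 at 3.93 (0.049) and Thbs1 at 3.19 (0.031) still passed. Without cytosol replicate 1 Hspa5 stood at 7.80, and without ER replicate 2 Hspa5 (0.11), Col2a1 (0.058) and P4hb (0.058) did not pass. Among the lowest were the cell cycle protein Cks2 at -2.53, the proteasome subunit Psma5 at -2.44, Rps27a at -2.37, Cdc16 at -2.30 and Ola1 at -2.29. None of these 5 passed without ER replicate 2, where Cdc16 stood at -1.41 and Ola1 at -1.45. Of them Psma5 alone passed without cytosol replicate 2, and Psma5 and Rps27a without cytosol replicate 1.

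All 19 ER chaperones were higher in the ER (median 4.47, set adjusted p = 1.1e-27, 19 up adjusted over the list alone). So were 36 of 37 matrix and secreted proteins (median 4.80, set adjusted p = 1.6e-47, 36 up adjusted over the list alone) and 22 of 23 receptors (median 4.22, set adjusted p = 1.9e-31, 23 up adjusted over the list alone), with Itgb1 at 5.54 and Lrp1 at 5.19, or 3.27 (adjusted p = 0.063) and 3.86 (0.066) without cytosol replicate 2. Without ER replicate 2 these counts were 10, 22 and 9, and without cytosol replicate 2 they were 7, 16 and 5, with medians of 2.73, 3.19 and 2.88. ER-associated degradation had 6 of 12 up and 8 up and 1 down adjusted over the list alone, with Vimp at 4.64 (median 1.98, set adjusted p = 2e-09, adjusted p = 0.1 with an estimated correlation). Translocation and transport had 17 up and 2 down of 36, and 18 up and 7 down adjusted over the list alone, with the channel subunit Sec61a1 at 5.21 (median 1.49, set adjusted p = 1.5e-09, adjusted p = 0.072 with an estimated correlation). Abundant cytosolic proteins had 14 of 35 down and 25 adjusted over the list alone (median -1.23, set adjusted p = 0.00028, adjusted p = 0.18 with an estimated correlation). Ribosomal proteins had 27 of 81 down and 36 adjusted over the list alone (median -1.23, set adjusted p = 1.8e-05, adjusted p = 0.35 with an estimated correlation). Translation factors had 12 of 35 down, with Eif2s3x at -2.07, and 1 up and 20 down adjusted over the list alone (median -1.25, set adjusted p = 0.0084, adjusted p = 0.1 with an estimated correlation). The cell cycle list had 12 of 32 down, with Cdk1 at -1.74, and 18 adjusted over the list alone (median -1.20, set adjusted p = 0.002, adjusted p = 0.1 with an estimated correlation). IRE1 substrates had 5 of 8 up and 6 adjusted over the list alone (median 3.70, set adjusted p = 1.3e-06, adjusted p = 0.1 with an estimated correlation). Fibroblast markers had 4 of 8 up, and 4 up and 1 down adjusted over the list alone (median 3.31, set adjusted p = 0.00022, adjusted p = 0.1 with an estimated correlation). NF-kB and cytokine genes had 2 of 8 up, Csf1 at 3.87 and Ptgs2 at 3.43 (1.84 without cytosol replicate 2), also adjusted over the list alone (median 0.93, set adjusted p = 0.014, adjusted p = 0.48 with an estimated correlation). Histones had 2 up and 2 down of 45 and 0 adjusted over the list alone (median -0.46, or -0.73 without cytosol replicate 2, set adjusted p = 0.43, with the test pointing up). Without ER replicates 1 and 2 and cytosol replicate 2 the falls were 4, 0 and 0 in cytosolic proteins, 7, 0 and 5 in ribosomal proteins, 3, 0 and 3 in translation factors and 3, 0 and 0 in the cell cycle list, which had 1 without cytosol replicate 1. ER-associated degradation had 14 up without cytosol replicate 1 and 3 without replicate 2 of either fraction. Its median was 3.28 without cytosol replicate 1 and 1.06 without cytosol replicate 2, and that of translocation and transport was 2.26 and 0.86. Fibroblast markers had a median of 1.09 without cytosol replicate 2. NF-kB genes had medians of 3.24 and -1.58 without ER replicates 1 and 2 and of 0.47 and -0.45 without cytosol replicates 1 and 2, and the set test passed 0.05 before adjustment in the first of these only. Translocation and transport had 10 and 11 up, IRE1 substrates 3 and 2, and NF-kB genes 0 and 0 without replicate 2 of the ER and of the cytosol. Eef1a1 at -1.18 (adjusted p = 0.059) and Ddit3 at -0.42 (0.48) did not pass.

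Over 5786 genes limma called 465 higher and 500 lower in the ER, with the median gene at -0.79. Median centring gave 483 higher and 155 lower, and the fit without the weight per fraction 474 higher and 136 lower. Voom gave 591 higher and 62 lower. The replicate block tilted the other way, with 509 higher and 1319 lower, and a block per time gave 527 higher and 1312 lower. The balance thus depends on the fit, and the pairing check did not pass for this one. Falls that were lost with centring include the tRNA synthetases Wars (adjusted p = 0.099) and Dars (0.073) and the sterol enzyme Lss (0.15). The total was 468 and 201 without ER replicates 1 and 2, and 211 without cytosol replicate 2. In mRNA of untreated cells limma called 2 of 1727 genes higher in the ER, the ribosome receptor Rrbp1 at 4.75 and LOC101055785 at 4.22 (adjusted p = 0.047 for both, the latter named after its value was seen), and 0 lower, with 97 at an unadjusted p under 0.05, 10 by voom and the median gene at -0.61. The count was 0 without replicate 1 of the ER or replicate 2 of the cytosol, and 1 without either other library. The replicate block gave 34 higher and 12 lower, among them Hsp90b1 at 4.48 (adjusted p = 1.3e-05), Calr at 3.78 (3.9e-05) and Col1a2 at 3.82 (0.00075). Matrix mRNAs stood higher as a set (16 measured, 0 past the test, 8 up adjusted over the list alone, median 2.41, set adjusted p = 2.2e-20).

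**Figure D3:**
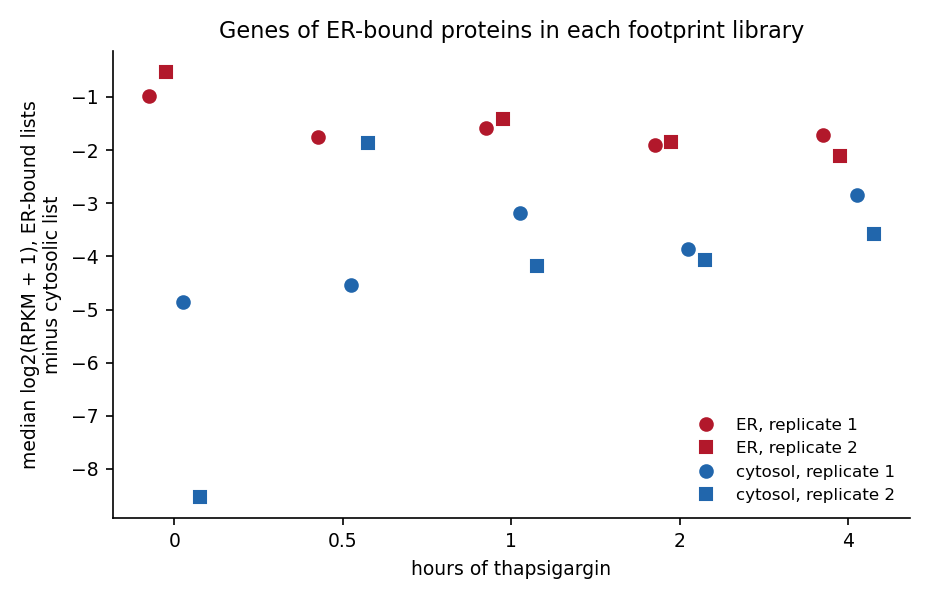
Median log2(RPKM + 1) of genes of 3 ER-bound lists minus that of abundant cytosolic proteins (vertical axis) in each footprint library, against hours of thapsigargin. Cytosol untreated replicate 2 lies at -8.52, and the library labelled cytosol footprints 0.5 h, replicate 2, lies at -1.87 within the range of -2.11 to -1.41 of ER libraries after thapsigargin.

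The fourth comparison asks whether footprints moved between the fractions during stress, as the change of the ER-to-cytosol ratio against untreated cells. Matrix proteins, ER chaperones and receptors fell in this ratio as sets at 4 h, but few of their members passed and each set had an adjusted p = 0.1 with an estimated correlation. Without cytosol untreated replicate 2 their medians lay between -1.66 and -1.89 in place of -3.30 to -3.64. At 4 h the largest falls of the ratio were the matrix protein Sparc at -5.15 (limma adjusted p = 0.049; -3.25 without cytosol untreated replicate 2), Cyba at -5.00, the retrieval receptor Kdelr2 at -4.62 (0.031), Ly6e at -4.51, Bcap31 at -4.42 and Atp1b3 at -4.37. The ratio of the splicing factor Srsf10 rose by 2.95 and that of Racgap1 by 2.14. At 1 h the largest falls were Sparc at -5.17, Fkbp9 at -5.15, Rcn1 at -5.11, Ssr1 at -5.01 (-3.27 for Sparc and -3.31 for Ssr1 without cytosol untreated replicate 2), Cd44 at -4.87 and Kdelr1 at -4.86, of which Fkbp9 passed with median centring (adjusted p = 0.046) and the others did not. Hspa5 at -3.35 (adjusted p = 0.23) and Col1a1 at -3.91 (0.21) did not pass at 4 h, and neither did Ddit3 at -0.20.

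At 4 h matrix and secreted proteins had 3 of 32 down and 12 adjusted over the list alone (median -3.38, set adjusted p = 6.3e-24, adjusted p = 0.1 with an estimated correlation). ER chaperones had 1 of 18 down, Hspa13 at -3.61, and 14 adjusted over the list alone (median -3.64, set adjusted p = 3.5e-16, adjusted p = 0.1 with an estimated correlation). Receptors had 0 of 19 down and 14 adjusted over the list alone (median -3.30, set adjusted p = 3.1e-16, adjusted p = 0.1 with an estimated correlation). Without cytosol untreated replicate 2, which stood at an index of -8.52 against -4.85 for replicate 1, these medians were -1.66, -1.71 and -1.89. Without cytosol untreated replicate 1, 27, 15 and 14 members passed, and without any other library 0 matrix genes did.

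Over all genes limma called 0 up and 55 down of 4043 at 0.5 h, 0 up and 79 down of 3207 at 1 h, 4 up and 48 down of 2908 at 2 h and 5 up and 32 down of 2725 at 4 h. The rises at 2 h were Arhgef1, Rrp12, Wasf2 and Wdr6, and those at 4 h Ap2a1, Gm5528, Racgap1, Srsf10 and Usp5, named after their values were seen except for Srsf10 and Racgap1. The median gene stood at -0.13, 0.06, 0.42 and 0.75. At 0.5 h the ER has 1 library, and the cytosol includes the library in doubt, labelled cytosol footprints 0.5 h, replicate 2. The balance at 4 h depends on the fit, with 136 up and 124 down with the replicate block. A block per time gave 114 up and 167 down at 4 h. At 2 h the replicate block gave 22 up and 114 down. The pairing check did not pass for this fit. The calls at the early times depend on the scaling. Without the weight per fraction there were 0 and 0 at 0.5 and 1 h and 6 up and 53 down at 4 h, and median centring gave 0 at 0.5 h, 0 up and 24 down at 1 h and 8 up and 77 down at 4 h. The totals were 497, 450, 336 and 323 without cytosol untreated replicate 1. At 0.5 h the total was 221 without cytosol thapsigargin replicate 1 and 0 without any remaining library. At 1 h it was 21 without ER thapsigargin replicate 1, 59 without cytosol thapsigargin replicate 2 and 0 without any remaining. At 2 h it was 16 without ER untreated replicate 1, 2 without cytosol untreated replicate 2 and 0 without any remaining, and at 4 h 2 without cytosol thapsigargin replicate 2 and 0 without any remaining.

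The fifth comparison asks which genes gained or lost footprints per mRNA. In the fit without a replicate block Ddit3 was the only gene whose translational efficiency passed the test, in the cytosol at 2 and 4 h. Its log2 change there was 5.55 at 2 h (limma adjusted p = 0.019) and 5.55 at 4 h (SE 0.86, adjusted p = 0.016), against 4.86 at 1 h (adjusted p = 0.071). With a replicate block per time 0 genes passed at 2 and 4 h, and Ddit3 had an adjusted p = 0.13 at 4 h. A block per assay gave the cytosol 4 up and 0 down at 0.5 h and 2 up and 0 down at 1 h. At 2 h it gave 7 up and 1 down, and at 4 h 24 up and 1 down. The pairing check passed in cytosol mRNA but not in cytosol footprints. Ddit3 mRNA in the cytosol went from 108 ± 34.3 to 116 ± 38.5 RPKM (SD, n = 2 each). Atf4 had 4.27 (adjusted p = 0.25) and Atf5 5.25 (0.55) at 4 h, and none passed. In the ER Ddit3 had 5.83 (0.21, but 0.034 with median centring), Gadd45b 3.66 (0.3, but 0.034 with centring) and Atf4 3.86 (0.49). Upstream reading frame mRNAs rose as a set in the cytosol at 4 h (1 of 8 up, 5 up adjusted over the list alone, median 2.56, set adjusted p = 6.6e-05). In the ER they had 0 of 7 up and 4 up adjusted over the list alone (median 2.02, set adjusted p = 8.7e-05). Matrix and secreted proteins in the ER had 0 of 26 past the test and 5 down adjusted over the list alone (median -1.66, set adjusted p = 2.4e-07, adjusted p = 0.15 with an estimated correlation), with Fn1 at -3.50 (adjusted p = 0.48).

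In the cytosol limma called 0, 0, 1 and 1 genes of 1815, 1702, 1877 and 1730 at 0.5, 1, 2 and 4 h, against 69, 90, 111 and 104 at an unadjusted p under 0.05, and voom called 0, 0, 1 and 1. The call at 4 h was lost without replicate 1 of cytosol footprints at 4 h, replicate 2 of either assay at 4 h, or untreated replicate 2 of either assay. At 2 h it was lost without any 1 of the libraries of 2 h or untreated replicate 2 of either assay, and at 0.5 h there was 1 call without cytosol footprints 0.5 h, replicate 1. The median gene stood at 0.21, 0.48, -0.05 and 0.47. In the ER limma called 0 of 341, 1329, 1101 and 903, against 32, 103, 53 and 48 at an unadjusted p under 0.05, and voom called 0. The numbers pair the samples within each assay of the ER, and a replicate block per assay gave 0 up and 0 down, 2 up and 16 down, 0 up and 0 down, and 4 up and 1 down, with Ddit3 past the test at 1 h (adjusted p = 0.044) and 4 h (0.029). The ER totals were 132 without ER mRNA 0.5 h, replicate 1, at 0.5 h, 12, 6 and 6 without ER mRNA untreated replicate 1 at 1, 2 and 4 h, and 1 without ER mRNA 4 h, replicate 1, at 4 h. The median gene stood at -1.74, -0.71, -0.29 and -0.33, and median centring gave 3 up at 4 h.

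The sixth comparison asks which mRNAs changed. Over the 4 times limma called 0 mRNAs in the ER (of 418, 2014, 1690 and 1385) and 0 in the cytosol (of 2136, 1923, 2322 and 2177). At an unadjusted p under 0.05 there were 9, 19, 7 and 10 in the ER and 68, 127, 132 and 305 in the cytosol, and voom called 0 in both. The same-numbered libraries pair, and with the replicate block the cytosol had 14 up and 5 down, 16 up and 35 down, 25 up and 62 down, and 30 up and 477 down, while the ER still had 0. The median gene of the ER stood at 1.12, 0.15, 0.05 and 0.22 and that of the cytosol at -0.35, -0.69, -0.52 and -0.91, and the block with median centring gave 19 up and 3 down, 29 up and 4 down, 46 up and 20 down, and 85 up and 51 down. In the blocked fit at 4 h these ER chaperone mRNAs were higher: Hsp90b1 at 3.18 (adjusted p = 0.00065 with the block, 0.36 without), Calr at 2.30 (0.0034 and 0.4) and Hspa5 at 1.45 (0.045 and 0.46). Lower in the blocked fit were Actb at -2.65 (0.00068 and 0.28) and Prdx1 at -3.52 (0.0032 and 0.28), where the median gene stood at -0.91. Ddit3 was at 0.09 and Atf4 at -0.83, and neither passed in either fit. ER chaperones rose as a set (4 measured, 0 past the test, also adjusted over the list alone, median 2.32, set adjusted p = 9.2e-06, adjusted p = 0.075 with an estimated correlation). Matrix mRNAs (15 measured, 0 past the test, also adjusted over the list alone) had a median of 0.14 (set adjusted p = 0.00098, adjusted p = 0.18 with an estimated correlation). Abundant cytosolic proteins (35 measured, 0 past the test, also adjusted over the list alone) had a median of -1.56 (set adjusted p = 0.00069, adjusted p = 0.34 with an estimated correlation). In the ER no list passed at 4 h, and the total at 0.5 h was 40 without thapsigargin replicate 1, which leaves a library of 1502 reads. The shift of mRNA between fractions had 0 calls of 339, 1292, 1254 and 1011, with 30, 77, 38 and 107 at an unadjusted p under 0.05, and voom called 1, 0, 0 and 0. With the replicate block it had 0 up and 3 down, 3 up and 5 down, 1 up and 9 down, and 19 up and 7 down, and 58 in all at 0.5 h without ER mRNA 0.5 h, replicate 1. The median gene of this shift stood at 1.39, 0.91, 0.54 and 1.11, and the block with median centring gave 1 up and 7 down, 2 up and 24 down, 1 up and 11 down, and 3 up and 19 down. A block per time gave 0 up and 4 down at 4 h, so the direction of the calls at 4 h depends on the fit.

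With an estimated correlation in place of the preset one, these set calls held. In ER footprints histones, immediate early genes, upstream reading frame mRNAs, ER chaperones, matrix and secreted proteins and receptors held at all 4 times. Fibroblast markers held at 0.5, 2 and 4 h, translation factors at 0.5 h, ribosomal proteins at 1 h and IRE1 substrates at 4 h. In cytosol footprints histones and immediate early genes held at 1, 2 and 4 h, sterol synthesis at 1 and 2 h, and the cell cycle list at 0.5 and 4 h. In cytosol mRNA receptors held at all 4 times and ER chaperones and matrix proteins at 0.5, 1 and 2 h. In the translational efficiency of the cytosol upstream reading frame mRNAs held at all 4 times and targets of ATF4 and CHOP at 0.5, 1 and 2 h. In untreated cells ER chaperones, matrix proteins and receptors held in footprints and matrix proteins in mRNA, and in the shift of footprints translocation and transport held at 1 h. For upstream reading frame mRNAs, receptors and immediate early genes in the translational efficiency of the ER, and for receptors in the ratio and shift of mRNA, no correlation was estimated.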

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

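Chosen only after the result was seen were the tests of dilution and of thapsigargin on the marked genes, the exact tests of their share in the cytosol and the 3 tests on histones.

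In the library labelled cytosol footprints 0.5 h, replicate 2, genes of ER-bound lists stood at -1.87 against abundant cytosolic proteins (median log2 difference, 63 and 35 genes). The 7 ER libraries after thapsigargin lay between -2.11 and -1.41 and the 7 other cytosol libraries after thapsigargin between -4.54 and -2.84. A non-negative fit with the ER and cytosol profiles of 0.5 h, replicate 1, gave an ER share of 79.0% (bootstrap range 70.6 to 87.6%). An ER library under a cytosol label and ER material carried over into a cytosol library cannot be told apart from this share, since the ER library that would be its partner has no values. The same library is 1 of the 2 that listed Ppp1r15a, with 14 reads, and the origin of those reads was not tested. No biological explanation was tested for the library.

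Most matrix, receptor and ER chaperone genes of the lists carry the mark of the deposited table. Its share is therefore not independent of their results, although no comparison used the mark itself. Genes with the mark held a mean of 31.4% of the RPKM of ER footprints in untreated cells (lower 29.7%, n = 2) and 15.9% after thapsigargin (11.9 to 20.4%, n = 7). Untreated ER libraries thinned to 56857 reads kept at least 30.2% in 20 draws each, and without histones and the 10 largest genes of each library the lower untreated share was 31.6% against at most 25.5% after thapsigargin, which argues against depth and against a few large genes. Dilution by cytosolic material as the whole cause would move matrix and receptor genes alike, and their medians differed by 0.11, 0.16 and -0.12 at 0.5, 1 and 2 h (permutation p = 0.887, 0.591 and 0.671) and by -0.65 at 4 h (permutation p = 0.003, 36 and 25 genes). At 4 h matrix genes stood lower without any 1 library, at -1.75 against -1.38 and -1.74 against -0.86 without untreated replicates 1 and 2, and at -1.90 against -1.05 and -1.65 against -1.17 without thapsigargin replicates 1 and 2. The permutation shuffled genes, which are not independent replicates, so its p does not measure the spread between libraries. Only genes listed in every library compared entered, so genes that fell below the listing minimum are missing. A difference at 1 of 4 times does not exclude dilution at the others, so dilution and a treatment effect cannot be told apart here. Thapsigargin may lower the share, and the shares of the 2 kinds of library did not overlap, but 2 against 7 libraries can give no exact permutation p under 0.056, so that test decides nothing.

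In the cytosol the same genes held 5.3% in untreated cells (4.6 to 6.0%, n = 2) and 11% after thapsigargin (8.6 to 18.7%, n = 8, with 4 times pooled). The exact permutation p was 0.044, the smallest that 2 against 8 libraries can give. It says only that the shares of the 2 kinds of library did not overlap. The result is given here because no comparison used the mark. The value of 18.7% is the library labelled cytosol footprints 0.5 h, replicate 2, and without it the range is 8.6 to 11.3% (n = 7) with an exact permutation p of 0.056, the smallest that this number of libraries can give.

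Histone footprints rose in both fractions at 4 h relative to the other genes. Whether their absolute amount rose cannot be read from values scaled per library. The 5 linker histones, which are not among the core copies, had medians of 3.13 in the ER and 3.07 in the cytosol beside 3.14 and 3.48 for 40 core histones, which argues against reads shared between near-identical core copies. More cells in S phase would raise the cell cycle list, which stood at -0.66 in the cytosol (set adjusted p = 0.0027) and at 0.27 in the ER (set adjusted p = 0.61; 0.00 to 0.50 without 1 library), where the replication genes Mcm3 and Tk1 passed the test. Tk1 lost its call without any 1 of the 4 libraries and Mcm3 without 3 of them. The list holds genes of mitosis and of DNA replication, so more cells in S phase cannot be told apart from other causes by it. In replicate 1 the median footprint change exceeded the mRNA change by 2.80 in the ER (32 genes) and 2.01 in the cytosol (35 genes). More histone mRNA as the whole cause stays possible and cannot be told apart from more translation, since replicate 2 of untreated mRNA listed 4 and 3 histones against 39 and 37 in replicate 1.

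The change with thapsigargin differed between ER and cytosol footprints, by the interaction test, for 55, 79, 52 and 37 genes at 0.5, 1, 2 and 4 h. At 0.5 and 1 h this depends on the scaling, with 0 and 0 genes without the weight per fraction and 0 and 24 with median centring. Without cytosol untreated replicate 1 these were 497, 450, 336 and 323. At 0.5 h 221 passed without cytosol 0.5 h, replicate 1, at 1 h 21 without ER 1 h, replicate 1, and 59 without cytosol 1 h, replicate 2, at 2 h 16 without ER untreated replicate 1 and 2 without cytosol untreated replicate 2, and at 4 h 2 without cytosol 4 h, replicate 2. Without any other library of the comparison the count was 0. At 4 h the same test on lists gave median differences in footprints of -3.64 for ER chaperones, -2.24 for ER-associated degradation, -0.61 for translocation and transport, -3.38 for matrix and secreted proteins, -3.30 for receptors, 0.93 for the cell cycle list, -0.28 for histones and -3.16 for fibroblast markers. In mRNA they were -2.73 for ER chaperones, -0.22 for matrix and secreted proteins, -0.92 for receptors, 1.60 for abundant cytosolic proteins and 1.40 for ribosomal proteins. With an estimated correlation none of these calls at 4 h held in footprints (adjusted p from 0.1 to 0.46) or in mRNA (0.22 to 0.77, with none estimated for receptors). Without cytosol untreated replicate 2 the footprint medians were -1.71 in chaperones, -1.45 in degradation genes, -1.66 in matrix proteins, -1.89 in receptors, 0.03 in histones and -0.93 in fibroblast markers, whose set test then did not pass 0.05 before adjustment. Without cytosol untreated replicate 1 they were -1.27 in translocation genes, -0.62 in histones and -5.39 in fibroblast markers. Translocation genes stood at -1.99 and -0.18 without ER 4 h, replicates 1 and 2, and at -0.29 and -1.10 without cytosol 4 h, replicates 1 and 2. Histones stood at -0.16 and -0.18 without the same ER libraries and at -0.52 and -0.09 without the same cytosol libraries. The cell cycle list did not pass 0.05 before adjustment without ER untreated replicate 2 or ER 4 h, replicate 2.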

How the results depend on the processing

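Chosen only after the data were seen were the tests with blanks as 0, a mean of at least 50 RPKM, no weight per fraction, voom, the block with centring or per assay, and without the 2 libraries in doubt. No named gene past the threshold changed direction under any alternative run, and no list past it did with the block, median centring or an estimated correlation. Without 1 library, run for lists in footprints at 0.5 and 4 h and in untreated cells, the median of 4 lists past the threshold turned sign, and that of ribosomal proteins in the cytosol at 0.5 h went from -0.30 to 0.00 without untreated replicate 2. Matrix genes in the cytosol at 4 h went from 1.54 to -0.23 without untreated replicate 2, and NF-kB genes in the ratio of untreated cells from 0.93 to -1.58 and -0.45 without replicate 2 of the ER and of the cytosol. Abundant cytosolic proteins in the ER at 4 h went from -0.16 to 0.09 without untreated replicate 1, and histones in the shift at 4 h from -0.28 to 0.03 without cytosol untreated replicate 2. With blanks as 0 most calls in ER footprints were falls, such as 139 up and 565 down at 2 h in place of 368 up and 185 down. The deeper untreated libraries can give such falls in low genes through depth alone. For results past the threshold in neither fit the direction was not read. Of the counts of genes 381 stayed within 1.5 times and 205 moved. A count of 0 in both fits was taken as stayed, and many comparisons of mRNA and translational efficiency had 0 calls in the main fit. This tally therefore says little about how stable the counts of comparisons with calls were. Of the named genes 11626 stayed on their side of the threshold, 710 lost the call and 190 gained it. Of the values of lists 865 stayed, 58 lost the call, 54 of them with an estimated correlation, and 9 gained it. Counts that moved follow as totals by setting, and the cause was not tested except where said.

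Same-numbered libraries pair in the mRNA fits and in ER footprints. The replicate block gave totals of 19, 51, 87 and 507 in cytosol mRNA at 0.5, 1, 2 and 4 h, 196 and 868 in ER footprints at 0.5 and 1 h, 3, 8, 10 and 26 in the shift of mRNA and 46 in the ER-to-cytosol ratio of mRNA. Where the pairing check did not pass, it gave 276, 171, 1043 and 827 in cytosol footprints, 144, 142, 136 and 260 in the shift of footprints, 1828 in the ratio of footprints and 1 in cytosol translational efficiency at 1 h. The block gave 509 higher and 1319 lower in the ratio of footprints, in place of 465 and 500. In the shift of footprints at 4 h it gave 136 up and 124 down, in place of 5 and 32. The block ended the call of 0 named genes and gave 52 a call, and it changed no other count by over 1.5 times. With block and centring the totals were 22, 33, 66 and 136 in cytosol mRNA, 10 and 2 in ER mRNA at 1 and 4 h, 149, 832 and 886 in ER footprints at 0.5, 1 and 2 h, and 132, 1044 and 809 in cytosol footprints at 1, 2 and 4 h. They were 8, 26, 12 and 22 in the shift of mRNA, 0, 153 and 169 in that of footprints at 0.5, 2 and 4 h, 79 in the ratio of mRNA, 6, 7 and 12 in ER translational efficiency at 1, 2 and 4 h and 1 in that of the cytosol at 1 h. A block per assay gave 18 and 5 in ER translational efficiency at 1 and 4 h and 4, 2, 8 and 25 in that of the cytosol. A block per time gave 8, 4, 6 and 4 in the shift of mRNA, 0, 114 and 281 in that of footprints at 0.5, 2 and 4 h, 34 and 1839 in the ratios of mRNA and footprints, and 0 in cytosol translational efficiency at 2 and 4 h.

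Blanks as 0 gave 440 in ER footprints at 0.5 h, 88, 218 and 228 in cytosol footprints at 0.5, 2 and 4 h, 8, 47 and 5 in the shift of footprints at 0.5, 1 and 2 h, 0 and 530 in the ratios of mRNA and footprints, and 0 and 5 in cytosol translational efficiency at 2 and 4 h. At a mean of at least 50 RPKM, where fewer genes are tested, ER footprints had 162, 193 and 247 at 1, 2 and 4 h, cytosol footprints 117 and 270 at 1 and 2 h, the shift of footprints 32, 21 and 31 at 0.5, 1 and 2 h, the ratios 0 and 513, and cytosol translational efficiency 1, 2, 2 and 2. Without the weight per fraction ER footprints had 26 at 0.5 h, cytosol footprints 43 and 35 at 0.5 and 1 h, the shift of footprints 0, 0 and 59 at 0.5, 1 and 4 h, and the ratios 5 and 610. Voom gave 858 and 583 in ER footprints at 2 and 4 h, 702, 471 and 925 in cytosol footprints at 0.5, 1 and 4 h, 1 in the shift of mRNA at 0.5 h, 199, 365, 256 and 273 in that of footprints and 10 in the ratio of mRNA. Median centring gave 21 in ER footprints at 0.5 h, 1 in the shift of mRNA at 0.5 h, 0, 24 and 85 in that of footprints at 0.5, 1 and 4 h, 7 and 638 in the ratios and 3 in ER translational efficiency at 4 h. A pseudocount of 0.1 gave 3, 39, 34 and 18 in the shift of footprints, and one of 5 gave 109 and 71 at 0.5 and 4 h and 0 in the ratio of mRNA. Without the 2 libraries in doubt cytosol footprints had 0 and 48 at 0.5 and 1 h, the shift of footprints 0 and 71 at 0.5 and 4 h and the ratio of mRNA 4.

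Leaving out 1 library leaves a lone sample that is assumed to vary like the other groups. Totals then ranged from 0 to 0, 124 to 267, 136 to 380 and 489 to 957 in ER footprints at 0.5, 1, 2 and 4 h, and from 0 to 474, 0 to 420, 5 to 719 and 14 to 529 in cytosol footprints. In the shift of footprints they ranged from 0 to 497, 0 to 450, 0 to 336 and 0 to 323, and in the ratio of footprints from 201 to 1087. ER translational efficiency ranged from 0 to 132, 0 to 12, 0 to 6 and 0 to 6, and that of the cytosol from 0 to 1 at 0.5, 2 and 4 h. The ratio of mRNA ranged from 0 to 1, ER mRNA from 0 to 40 at 0.5 h and the shift of mRNA from 0 to 58 at 0.5 h.

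Depth limits which genes were tested. ER footprints had 4893 testable genes at 0.5 h and 3162 at 4 h, where the smallest library held 56857 reads. ER mRNA had 418 at 0.5 h, where replicate 2 held 1502 reads.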

Other observations

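The lists of this part were planned, and the times given here were chosen only after the results of all tests were seen.

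At 0.5 h histone footprints had a median log2 change of 1.5 in the ER (1 library, with the spread of the other groups; 2 of 45 past the test, Hist1h2bb and Hist1h2bf, 28 adjusted over the list alone, set adjusted p = 2.6e-27) and 2.01 in the cytosol (9 of 45, 32 adjusted over the list alone, set adjusted p = 2.6e-19, adjusted p = 0.059 with an estimated correlation). The cytosol value includes the library labelled cytosol footprints 0.5 h, replicate 2, without which the median was 2.41 and 0 of 45 passed. Histones also had 0 past the test without untreated replicate 2 or thapsigargin replicate 1 in the cytosol, or without either untreated library in the ER. Matrix and secreted proteins in the ER stood at -1.42 at 0.5 h, -1.46 at 1 h and -1.71 at 2 h, and receptors at -1.54, -1.62 and -1.59. Sterol synthesis genes stood at 0.42 in cytosol footprints at 1 h (11 measured, set adjusted p = 0.015) and at 1.08 at 2 h (1 of 11 up, set adjusted p = 0.0043).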
